A study of Arabidopsis thaliana with 18 samples.

How the data were processed

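RNA was measured in 18 shoot samples of Arabidopsis thaliana, 1 array per sample, in 6 groups of 3 that combine 250 mM NaCl, 500 mM NaCl or water with harvest at 3 h or 27 h. Per the labels, total RNA was extracted from shoots of 4-week-old plants, labelled with the dye Cy3 and hybridised to 1-colour Agilent oligonucleotide arrays. Per the file headers, the values are fluorescence intensity from Feature Extraction 10.7.3.1 with protocol GE1_107_Sep09, which subtracts background and writes a processed signal per spot. The deposited series matrix holds log2 values that the authors had shifted to the 75th percentile of each array and centred on the median of each probe. A rebuild of that matrix from the scanner files correlated with it at r between 0.999961 and 0.999998 per array, across probes. Its column medians ran from -0.177 to 0.643 and its largest absolute probe median was 1e-06. Because probe centring removes the level of each gene, the scanner files were used for every comparison and the matrix served as an alternative.

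Each array held 62976 spots, of which 1319 were control spots, and 43603 non-control probes. Gene names came from the reference table of loci and transcript accessions supplied with the files. Of the probes, 34285 matched 1 locus and 9318 matched none, and the accession of 1093 probes differed between 2 releases of the array design. No probe was saturated on any array, a count of 0 from the scanner's own saturation column. Spots called outliers by the scanner software were left out, between 3 and 29 per array. A probe was kept where the software called it well above background on 3 of 3 arrays of at least 1 group, which left 31904 probes, 27371 of them matched. The brightest kept probe stood for each locus, which left 19765 loci. The number of arrays, 3 per group, limits the precision of every value. The array probes were designed on an earlier genome build than that table, so no coordinates are given.

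The processed signal was put on the log2 scale and shifted so that the 75th percentile of each array was 0. Group means of all 18 arrays were fitted with limma 3.58.1 in R 4.3.3, with statmod 1.5.0 and the data.table package (1.17.8), and the figures were drawn with matplotlib 3.10.9 in python 3.11.15. The fit had 12 residual degrees of freedom and 3.72 prior degrees of freedom. A gene was called where the 2-sided p, adjusted by the Benjamini-Hochberg method over the 19765 genes, was under 0.05. The 9 contrasts were each salt concentration against water at each time, 500 mM against 250 mM at each time, the change of each salt response between the times, and water at 27 h against water at 3 h. The p-values measure only the spread between these samples, which may be technical, since the labels do not say whether the replicates were separate plants. On simulated arrays with 200 changed genes in each of 20 simulations, 21.8% of 2-fold and 75.5% of 4-fold changes were recovered for a contrast of 3 arrays against 3, with 5.69% false calls. For the change of a response between times the shares were 3.15% and 41.6%, with 5.65% false calls.

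Gene lists were written before the data were examined, as were the fit, the threshold, the settings to be varied and the rule for named genes. There were 24 lists with 480 written members. They covered ABA (abscisic acid) and dehydration induced genes, ABA synthesis, catabolism and transport, clade A PP2C phosphatases, PYR/PYL receptors, osmolyte synthesis, ion transport and the SOS pathway, stress transcription factors, heat shock, redox and detoxification, and photosynthesis. Further lists covered senescence, jasmonate, salicylate, ethylene, aquaporins, cell wall loosening, auxin induced genes, cytokinin response regulators, aliphatic glucosinolates, flavonoids, the circadian clock and the cell cycle. A pair of lists held markers of other tissues, root and flower or pollen. A list of cytosolic ribosomal proteins had 2 tested members, fewer than the 5 required, and gave no test. Each list was tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 24 lists. Camera compares a list with all other genes, so its calls are relative to them. On the simulated arrays a shifted list was called in 20 of 20 runs and other lists in 0 of 460 tests. Genes varied independently in these runs, which therefore do not test false calls of lists whose genes are correlated.

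Genes were named by a rule with these parts. They were the 8 largest rises and 8 largest falls called in each of the 4 contrasts of salt against water, and the 4 largest in each direction in the 5 other contrasts. From each list and contrast came up to 4 called members with the largest change, or the 1 member with the smallest p where none was called. The last part was a set of 19 genes fixed in advance, RD29A, RD29B, RAB18, NCED3, HAI1, P5CS1, PRODH1, PRODH2, P5CDH, SOS1, HKT1, NHX1, DREB2A, ZAT12, HSFA2, LHCB1.3, RBCS1A, CCA1 and TOC1. Where a gene was above background on 0 arrays of the dimmer group, the fold is a lower bound. It sets the mean of the brighter group against the mean of the dimmer group after each dim value was raised, array by array, to the lowest signal among probes well above background, or kept where the probe's own signal was higher.

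The arrays came from 3 slides, read from the scanner headers, with 8, 8 and 2 arrays. Slide was fitted as a fixed and as a random block, and contrasts were repeated within 1 slide where it held both groups. Other settings chosen in advance were quantile normalization, normexp background correction with an offset of 50, the series matrix values, other filters, outlier spots kept, the mean of all probes of a gene, a trended robust variance, only the groups compared, an adjusted p under 0.01, the replicate number as a block, and leaving out each array in turn. The mean spot signal that normexp was to use is not in the files, so the median signal was used, a choice made after seeing the data. Added after seeing the data were fits without arrays that stood apart, with array weights, and with signal strength as a covariate. Replicate numbers were checked for pairing in 7 contrasts by the correlation of same-numbered arrays, with a bound of 0.1 that every pair had to exceed. These correlations ran from -0.64 to 0.41, and 2 contrasts met the bound, 500 mM against water at 3 h and water at 27 h against 3 h. The growth conditions beyond soil culture and the pooling of plants are not given in the sources used here.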

Results

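Shoots of 4-week-old Arabidopsis plants of the laboratory accession Col-0 were measured on 18 arrays. Soil-grown plants had been flooded with a moderate salt solution (250 mM NaCl), a high one (500 mM NaCl) or water, and were harvested at 3 h or 27 h, with 3 arrays in each of 6 groups. Between 56.54% and 74.89% of the probes of an array were well above background. The 75th percentile of the processed signal ran from 198 in 500 mM NaCl 27 h, replicate 3, to 2373 in water 3 h, replicate 1. Control transcripts added to the labelling reaction had median signals of 5951 and 5172 in water 3 h, replicates 1 and 2, against 267.2 to 1200 on the other arrays. Slide 1 held all salt arrays of 3 h with replicate 1 of each watered group. Slide 2 held all salt arrays of 27 h with 2 watered arrays of 27 h, and slide 3 held the other 2 watered arrays of 3 h. Watered arrays lay in column 4 of a slide, in both rows, while 250 mM NaCl lay in row 1 and 500 mM NaCl in row 2, at both times. Changes below are on the log2 scale with the standard error (SE) of the contrast, n = 3 arrays per group. Where a gene list lost its call once the correlation between its genes was estimated, that adjusted p stands beside it after the word correlated.

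The comparison of 250 mM NaCl with water at 3 h asked how shoots stood early after moderate salt. Genes of jasmonate synthesis and response, a hormone pathway of wounding and defence, lay higher by a median of 0.7, and 10 of 27 rose adjusted over the list alone, 0 over all genes (camera adjusted p = 2.5e-16). The clade A PP2C phosphatases, negative regulators of signalling by the drought hormone ABA, lay higher by a median of 0.91, and 4 of 9 rose adjusted over the list alone, 0 over all genes (8.8e-08). ABA and dehydration induced genes lay higher by 0.54, with 7 of 26 rising adjusted over the list alone, 0 over all genes (2.8e-11, correlated 0.073). ABA synthesis, catabolism and transport lay higher by 0.31 over 14 genes, with 0 called over the list alone (0.002). HAI1, a PP2C gene, differed by 2.71 (SE 0.59, adjusted p = 0.37) and CYP94B3, whose enzyme inactivates the jasmonate signal, by 2.61 (SE 0.52, adjusted p = 0.29). ERF109, an ERF transcription factor, was above background on no watered array and at least 5-fold higher in salt (adjusted p = 0.27). NCED3, of ABA synthesis, differed by 0.97 (SE 0.40, adjusted p = 0.98) and ZAT12, a zinc finger gene, by 1.48 (SE 0.68, adjusted p = 0.98). PRODH1, of proline breakdown, differed by -1.11 (adjusted p = 0.98), RD29A by 0.44, RAB18 by -0.33, HSFA2 by -0.023 and DREB2A by -0.0036.

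Limma called 0 of 19765 genes at 3 h of 250 mM NaCl. The smallest adjusted p was 0.27, and 726 genes had an unadjusted p under 0.05. With array weights, chosen after seeing the data, limma called 1791, and without 250 mM NaCl 3 h, replicate 2, it called 2. Every other setting gave 0, slide as a block and within slide 1 included, with 327 and 615 genes at an unadjusted p under 0.05.

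Among other lists at 3 h of 250 mM NaCl, stress transcription factors lay higher by a median of 0.41 (camera adjusted p = 1.6e-05, correlated 0.073), with ABF3 at 0.57. Photosynthesis genes lay higher by 0.31 (1.4e-06, correlated 0.35), with LHCB2.1 at 1.12, but by -0.013 after quantile normalization. Aquaporins lay higher by 0.37 (4e-06, correlated 0.25), osmolyte synthesis by 0.45 (0.0033, correlated 0.08, GOLS3 at 0.83), flavonoid synthesis by 0.37 (0.0029, correlated 0.25, PAP1 at 0.91), redox genes by 0.19 (0.01, correlated 0.44), ethylene genes by 0.19 (0.014, correlated 0.25) and cell wall loosening by 0.17 (0.01, correlated 0.53). Aliphatic glucosinolate genes, which make sulphur-rich defence compounds, lay lower, with a median of -0.33 (0.0039, correlated 0.38, MAM3 at -0.88), and ion transport and the SOS pathway likewise, at -0.14 (0.047, correlated 0.25, CAX1 at -0.58). Adjusted over the list alone, 1 gene rose in each of osmolytes, ethylene and flavonoids and 0 in stress factors, photosynthesis, aquaporins, redox, cell wall, glucosinolates and ion transport. Camera called 14 of 24 lists, 12 of them upward. With an estimated correlation, 3 calls held, at an adjusted p of 0.035 for ABA synthesis, 0.035 for PP2C and 0.013 for jasmonate, and the same 3 with fry.

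In the slide-blocked fit, the 250 mM NaCl list medians at 3 h were 0.58 for jasmonate, 0.96 for PP2C and 0.83 for ABA-induced genes. That fit and the one within slide 1 use the same watered array, so they are not separate checks. ABA synthesis and ethylene lost their calls in both, ion transport and redox within slide 1. Quantile normalization ended the calls of redox (0.26, median 0.074), ion transport (0.09) and photosynthesis (0.82), and normexp that of ethylene (0.062). With 1 array left out, 9 calls held each time. Lost were osmolytes without water replicate 2 (0.1), redox without 250 mM replicate 3 (0.16), ethylene without water replicate 3 (0.055), cell wall loosening without water replicates 1 and 3 or 250 mM replicate 1 (0.089, 0.12, 0.095) and ion transport without these or 250 mM replicate 2 (0.1, 0.058, 0.086, 0.069). The salicylate list, of a defence hormone, had a median of 0.056 (camera adjusted p = 0.64), but -0.46 with slide as a block (0.01), and it was called without water replicate 1 (0.014) and 250 mM replicate 1 (0.011), and downward without 250 mM replicate 3 (0.028). Medians were -0.027 for PYR/PYL receptors (0.58), 0.13 for heat shock (0.84), 0.14 for auxin induced genes (0.23), -0.0058 for cytokinin regulators (0.58) and -0.13 for the cell cycle (0.051). Senescence genes had a median of 0.17 and a mean of -0.013 (0.73), and the circadian clock had a median of 0.00056 and a mean of -0.07, its test pointing downward (0.84). Markers of other tissues lay at 0.31 for root (0.053, PRP3 at 2.02 with 2 watered arrays above background) and 0.21 for flower or pollen (0.13, EXL4 at 1.80 with 2 watered arrays above background). The root and flower lists were called with slide as a block, both at 0.027, with medians of 0.48 and 0.42, and without water replicate 3 (0.011 and 0.016), and root markers without 250 mM replicate 1 (0.038). The cell cycle was called without water replicate 1 (0.035) or 3 (0.043) or 250 mM replicate 2 (0.025) and with normexp (0.046).

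After 500 mM NaCl for 3 h, LEA7, a protective late embryogenesis abundant gene, rose by 10.5 (SE 0.91, adjusted p = 1.2e-06). LEA7 was above background on 2 of 3 watered arrays. RAP2.6, ERF109 and ABR1, transcription factors of the ERF family, rose at least 96.9-fold, at least 101-fold and at least 128-fold. BSMT1, which methylates benzoate and salicylate, rose at least 56.9-fold. UGT76E12, a glycosyltransferase gene, rose by 8.47 (SE 0.66, adjusted p = 5e-07, 1 watered array above background), CYP94B3 by 7.83 (SE 0.52, adjusted p = 1.5e-07) and ELI3-2, an alcohol dehydrogenase gene, by 7.66 (SE 0.41, adjusted p = 4e-08). The largest falls included EXPA8, an expansin, at -3.59 (SE 0.45, adjusted p = 4.3e-05), GASA6 at -2.91 (SE 0.40), PRE1 at -2.85 (SE 0.57, adjusted p = 0.0025) and HMA2, a zinc pump, at -2.81 (SE 0.57). GA20OX3, of gibberellin synthesis, fell at least 3.56-fold and the receptor gene PYL6 at least 1.3-fold. DOT3 and EMB3120 fell by 2.77 and 2.72 on the log2 scale, each with 1 salt array above background. In the slide-blocked fit, PRE1 (-2.37, adjusted p = 0.12), HMA2 (-2.88, 0.074), DOT3 (-2.71, 0.11), EMB3120 (-2.85, 0.089), GA20OX3 (0.069) and PYL6 (0.054) were no longer called. The SE grew there by a median of 1.51 times. With normexp GA20OX3 (0.24), PYL6 (0.77), DOT3 (0.14) and EMB3120 (0.072) were not called either, and DOT3 was lost without 500 mM NaCl 3 h, replicate 2 (0.062).

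Among the genes fixed in advance, HAI1 rose by 7.58 (SE 0.59, adjusted p = 4.9e-07) at 3 h of 500 mM NaCl and NCED3 by 3.58 (SE 0.40, adjusted p = 1.6e-05). ZAT12 rose by 4.79 (adjusted p = 0.00013), HSFA2, a heat shock factor, by 4 (SE 0.37, adjusted p = 2.4e-06), DREB2A by 2.46 and PRODH2 by 3.39 (adjusted p = 0.00011). RD29B rose by 2.53 (adjusted p = 0.0012) and NHX1, a vacuolar sodium exchanger, by 1.52 (SE 0.38, adjusted p = 0.0092). With slides blocked, both were no longer called (1.98 at 0.068 and 1.65 at 0.13), and NHX1 was lost without 500 mM NaCl 3 h, replicate 2 (0.057). RD29A differed by 1.07 (adjusted p = 0.12), though it was called without water 3 h, replicate 3 (0.047). RAB18 differed by 0.26 (0.53), P5CS1 by 0.99 (0.11), SOS1 by -0.45 (0.47), HKT1, a sodium transporter, by -0.93 (0.087), and PRODH1 by 0.046. LHCB1.3 differed by 0.48 (0.42), RBCS1A by 0.20 (0.66), CCA1 by 0.24 (0.78), TOC1 by 0.56 (0.12) and P5CDH by -0.62.

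Limma called 5442 of 19765 genes for 500 mM NaCl at 3 h, with 2507 rising and 2935 falling, of which 2022 and 1791 changed at least 2-fold. The median over all genes was -0.15, -0.18 after quantile normalization and -0.036 after normexp, and changes are relative to it. In a slide-blocked fit, 985 genes were called, 844 of them rising, and within slide 1, which held 1 watered array, 708. Without water 3 h, replicate 1 or replicate 3, the count was 3583 or 3524, and without 500 mM NaCl 3 h, replicate 1 or replicate 2, it was 3138 or 2626. Without both watered arrays of high control signal, a choice made after seeing the data, it was 1457, a fit with 1 watered array of 3 h, assumed to vary like the others. The arrays met the bound for pairing here, and with the replicate block 5259 genes were called.

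At 3 h of 500 mM NaCl, 21 of 26 ABA and dehydration induced genes rose (22 adjusted over the list alone, median 2.2, camera adjusted p = 1.9e-18), with LEA4-5 at 7.39, TSPO at 6.01 and LTP4 at 5.33. All 9 PP2C genes rose by both adjustments (median 2.8, 1.7e-10), HAB1 by 3.96. Of 30 stress transcription factors 23 rose (25 adjusted over the list alone, median 2.5, 3.5e-17), among them CBF4 by 4.95 and WRKY40 by 4.41. Of 27 jasmonate genes 22 rose (23 adjusted over the list alone, median 1.9, 2.7e-16), JAZ7 by 5.15, AOC3 by 4.93 and JAZ5 by 4.29. Of 14 genes of ABA synthesis, catabolism and transport 7 rose and 1 fell (8 and 1 adjusted over the list alone, median 1.3, 3.1e-05), CYP707A3 rising by 3.82. Senescence genes rose in 13 of 26 cases with 1 fall (14 and 2 adjusted over the list alone, median 1.1, 2.3e-06, correlated 0.085), WRKY75 by 4.86 and SAG13 by 4.52. Redox genes rose in 14 of 24 cases (16 adjusted over the list alone, median 1, 9.8e-08, correlated 0.085), GSTU3 at least 24.7-fold and GSTU4 by 4.97. Salicylate genes rose in 9 of 16 cases (10 adjusted over the list alone, median 1.4, 2.4e-05, correlated 0.3), FMO1 by 4.13, ALD1 by 3.65, PBS3 by 3.6 and ICS1 by 2.55, but 0 of them was called with slide as a block (median 0.79).

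Heat shock genes had 8 rises and 1 fall at 3 h of 500 mM NaCl (9 and 1 adjusted over the list alone, median 0.88, camera adjusted p = 0.00054, correlated 0.085), HSP17.8 rising by 3.56. Ethylene genes had 9 rises and 1 fall by both adjustments (median 0.49, 0.00022, correlated 0.085), ACS2 rising by 5.6. Aquaporins had 8 rises and 1 fall (the same counts adjusted over the list alone, median 0.63, 0.00074, correlated 0.33), PIP2;3 rising by 2.58. Flavonoid genes had 7 rises (10 adjusted over the list alone, median 0.92, 4.9e-05, correlated 0.085), PAP2 at least 30.1-fold and PAP1 by 2.49. Glucosinolate genes had 9 falls (11 adjusted over the list alone, median -1.6, 5.5e-05, correlated 0.19), MAM3 at -2.60 and MYB28 at -2.05. Cell cycle genes had 7 falls by both adjustments (median -0.54, 0.0056, correlated 0.2), MCM2 at -1.84. Lists without a call were osmolytes (median 0.4, 3 rises, RS5 at 2.62), ion transport (-0.47, 5 rises and 3 falls, CAX3 at 3.01, SLAH3 at 2.21) and PYR/PYL receptors (-0.23, 1 rise and 3 falls). Photosynthesis had 4 falls, PORB at -1.92, with a median of 0.094, -0.3 after quantile normalization, a mean of -0.064 and an upward test (0.93). Cell wall loosening had 4 rises and 5 falls, XTH22 at 2.64 and XTH33 at -2.61, with a median of -0.025 and an upward test (0.93). Auxin induced genes had a median of 0.16 (IAA29 at -1.54), cytokinin regulators -0.037 (ARR15 at -1.03), and the clock -0.29 with an upward test (0.8, ELF4 at 1.79, PRR7 at -1.43). JAZ7 was above background on 2 watered arrays and XTH33 on 1 salt array. Root markers had 1 rise, PRP3, and a median of 0.52 (0.2), and flower or pollen markers 1 rise, EXL4, a median of -0.047 and a mean of 0.35 (0.65).

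Of the 14 list calls at 3 h of 500 mM NaCl, 5 held with an estimated correlation, at an adjusted p of 0.011 for ABA-induced genes, 0.0049 for ABA synthesis, 0.0091 for PP2C, 0.0042 for stress factors and 0.0049 for jasmonate. Slide as a block leaves 1 watered array. Blocked medians were 2.1 for ABA-induced genes, 3 for PP2C, 2.4 for stress factors, 1.8 for jasmonate, 0.82 for ethylene and -1.5 for glucosinolates. Fewer members were called there. With normexp the cell cycle median was -0.32. Osmolytes were called without water replicate 1 (0.05) or 3 (0.024) or 500 mM replicate 2 (0.016). The fit within slide 1 uses the same watered array.

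**Figure D1:**
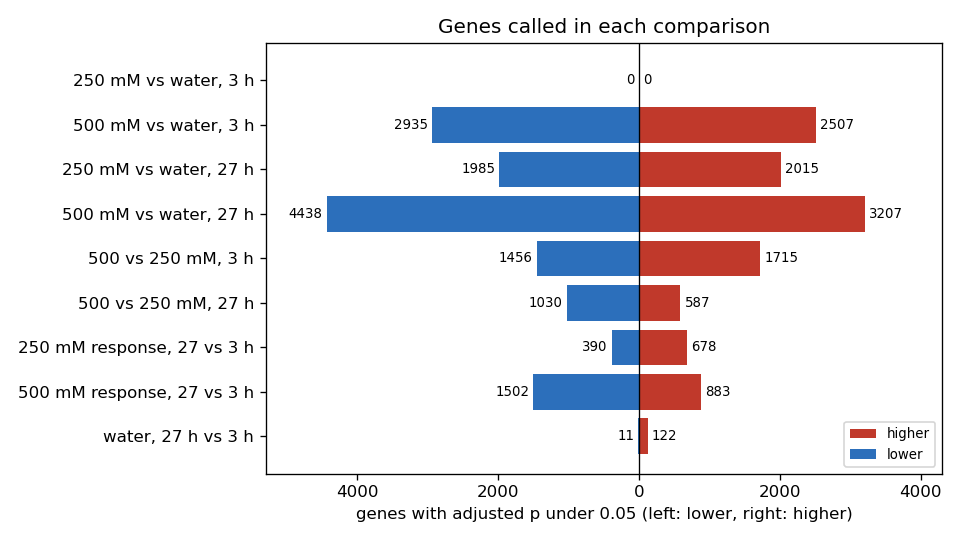
Number of genes called in each of the 9 contrasts, genes higher in the first-named group to the right of 0 and lower ones to the left, by limma on 3 arrays per group. The bar for 250 mM NaCl at 3 h is empty (0 genes), and that for 500 mM NaCl at 27 h reaches 3207 higher and 4438 lower.

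After 27 h of 250 mM NaCl, LEA7 rose by 10.2 (SE 0.91, adjusted p = 1.2e-06, 1 watered array above background). SAG29, a sugar transporter gene of senescing leaves, rose by 9.55 (SE 0.73, adjusted p = 1.9e-07), and GLYI7, a glyoxalase gene, by 8.67 (SE 0.42, adjusted p = 5.1e-09, 2 watered arrays above background). LTP4, of lipid transfer, rose by 8.54 (SE 0.36, adjusted p = 1.6e-09), LEA4-5 by 8.39 (SE 0.62) and ELI3-2 by 8.01 (SE 0.41). The nitrate transporter gene NRT1.8 rose at least 57.1-fold and RAP2.6 at least 53.5-fold. Falls included CYP81F2, of indole glucosinolates, at -4.12 (SE 0.32, adjusted p = 2.4e-07), EXPA8 at -3.80 (SE 0.45), the defensin PDF1.2 at -3.53 (SE 0.38, adjusted p = 6.1e-06) and GLL22 at -3.71 (SE 0.50). CYP81F2 and GLL22 were above background on 2 salt arrays. DIN11 fell at least 6-fold, PYL6 at least 2.76-fold and CYP96A5 at least 3.49-fold, and XND1 by 3.55 on the log2 scale with 1 salt array above background. With normexp PYL6 (0.44) and CYP96A5 (0.37) were not called.

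Of the genes fixed in advance, HAI1 rose by 7.28 (SE 0.59, adjusted p = 3.7e-07), NCED3 by 3.77 (SE 0.40, adjusted p = 6.5e-06), HSFA2 by 3.93 (SE 0.37), DREB2A by 3.12 and RD29B by 2.21 at 27 h of 250 mM NaCl. RAB18, a dehydrin, rose by 1.61 (SE 0.29, adjusted p = 8e-04) and NHX1 by 1.86 (SE 0.38, adjusted p = 0.0026). P5CS1, of proline synthesis, rose by 1.82 (SE 0.45, adjusted p = 0.0087), but was not called with slide as a block (1.67, 0.054). HKT1 fell at least 1.64-fold (adjusted p = 0.009), was not called without 250 mM NaCl 27 h, replicate 1 (0.052), and was at 0.031 with normexp (0.97). ZAT12 differed by 1.99 (0.051) and was called without water 27 h, replicate 2 (0.03), and after quantile normalization. RD29A differed by 0.66 (0.37), SOS1 by -0.55 (0.4), LHCB1.3 by 0.31 (0.64), RBCS1A by 0.24 (0.6), CCA1 by 0.49, TOC1 by -0.20 and PRODH1 by 0.069.

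Limma called 4000 genes for 250 mM NaCl at 27 h, with 2015 rising and 1985 falling, of which 1614 and 1426 changed at least 2-fold. The median over all genes was -0.12, -0.11 after quantile normalization and 0.023 after normexp. With slide blocked, 2617 were called, and within slide 2, which held 2 watered arrays, 1319. Without water 27 h, replicate 3, or 250 mM NaCl 27 h, replicate 3, the count was 2589 or 2500. Without the dimmest arrays of 500 mM NaCl and of water at 27 h, a choice made after seeing the data, it was 7190, and 5 root markers then rose (0 in the main fit, 1 after quantile normalization), with 15 cell cycle, 8 auxin induced and 7 ethylene genes lower and the clock at 4 rises and 4 falls.

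At 27 h of 250 mM NaCl, 21 of 26 ABA and dehydration induced genes rose (21 adjusted over the list alone, median 2, camera adjusted p = 1.1e-19), TSPO by 7.74. All 9 PP2C genes rose by both adjustments (median 3, 1.6e-12), AHG1 at least 15.3-fold. ABA synthesis, catabolism and transport had 6 rises and 1 fall by both adjustments (median 0.41, 0.00078), CYP707A1 at 3.98 and ABCG40 at -2.36. Stress transcription factors had 19 rises and 3 falls (21 and 3 adjusted over the list alone, median 1.5, 1.9e-08), DDF1 at least 19-fold and CBF4 by 5.14. Senescence genes had 13 rises and 3 falls (15 and 4 adjusted over the list alone, median 1.2, 2.3e-05, correlated 0.16), with NAC092 at 3.33 and DIN11 at least 6-fold lower. Aquaporins had 11 rises (12 adjusted over the list alone, median 0.92, 2.1e-07, correlated 0.18), TIP2;3 at 2.27, PIP1;4 at 2.04 and TIP1;1 at 1.90. Flavonoid genes had 9 rises (10 adjusted over the list alone, median 1.2, 2.8e-06, correlated 0.077), PAP2 at 3.78. Heat shock genes had 6 rises by both adjustments (median 0.55, 0.0081, correlated 0.23), HSP17.8 at 3.66, and redox genes 11 rises and 5 falls (12 and 5 adjusted over the list alone, median 0.58, 0.0098, correlated 0.48), FER1 at 2.88 and GSTF7 at -2.80.

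Salicylate genes had 8 falls at 27 h of 250 mM NaCl (10 adjusted over the list alone, median -1.4, camera adjusted p = 9.2e-05, correlated 0.41), EDS1 at -2.51, PAD4 at -2.09 and ICS1 at -1.99. Glucosinolate genes had 6 falls (7 adjusted over the list alone, median -1.1, 0.0024, correlated 0.38), SUR1 at -1.67. Cell cycle genes had 1 rise and 8 falls (2 and 11 adjusted over the list alone, median -0.9, 0.00076, correlated 0.17), MCM7 at -1.93. Photosynthesis genes had 10 falls of 38 (12 adjusted over the list alone, median -0.39, 0.0067, correlated 0.59), LHCB2.3 at -1.52. Jasmonate genes had 6 rises and 1 fall (median 0.13, 0.08), JAZ7 at 3.11. Ethylene genes had 6 rises and 3 falls (0.059, 0.35), with ACS7 at least 16.2-fold higher, and cell wall genes 7 rises and 2 falls (0.12, 0.06), EXPA10 at 3.90. Auxin induced genes had 5 falls (-0.38, 0.06), IAA29 at -3.50. Osmolyte genes had 3 rises and 1 fall with a median of -0.029 and a mean of 0.32 (0.38), RS5 at 1.99 and GOLS3 at -1.52. Ion transport genes had 5 rises and 4 falls with a median of -0.035 and a mean of 0.026 (0.44), SLAH3 at 2.74 and KAT1 at -2.17. The clock had 2 rises (median -0.077 with an upward test, 0.48), ELF4 at 2.33, and receptors 2 falls (-0.074, 0.44). Cytokinin regulators (0.21, ARR6 at 1.42), root markers (0.68, EXPA18 at least 1.54-fold higher) and flower or pollen markers (0.26, SEP3 at 0.97) had no called gene. Adjusted over the list alone, the counts changed to 7 falls for auxin, 7 rises and 4 falls for ethylene, 7 and 3 for cell wall genes and 4 and 2 for osmolytes, and were the same for jasmonate, ion transport, the clock and receptors.

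Of the 13 list calls at 27 h of 250 mM NaCl, 4 held with an estimated correlation, at an adjusted p of 0.019 for ABA-induced genes, ABA synthesis and stress factors and 0.016 for PP2C. All 13 held with slide as a block, with 4 photosynthesis genes called, and within slide 2, but photosynthesis was lost without water replicate 2 (0.054) and with fry (0.065). With normexp the cell cycle median was -0.36 with 4 falls. Block medians were 1.7 for ABA-induced genes, 3.1 for PP2C, 1.5 for stress factors, -1.3 for salicylate and 0.92 for aquaporins. The redox call was lost with normexp (0.088). Auxin was called after quantile normalization (0.035), with normexp (0.0075) and without water replicate 2 (0.028) or 250 mM replicate 2 (0.025) or 3 (0.046), cell wall loosening without water replicate 2 (0.019), jasmonate without water replicate 3 (0.023) and root markers without water replicate 2 (0.021) or 250 mM replicate 2 (0.046). CYP707A1 and PAP2 were above background on 2 watered arrays at 27 h.

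After 27 h of 500 mM NaCl, LEA7 rose by 12.9 (SE 0.91, adjusted p = 2.9e-08, 1 watered array above background) and SAG29 by 11.2 (SE 0.73, adjusted p = 1.3e-08). GLYI7 rose by 10.3 (SE 0.42), LEA4-5 by 9.58 (SE 0.62) and LTP4 by 9.13 (SE 0.36, adjusted p = 2.3e-10), while NRT1.8 rose at least 353-fold, BSMT1 at least 555-fold and RAP2.6 at least 262-fold. Among the largest falls, EXPA8 stood at -6.79 (SE 0.45, adjusted p = 1.6e-08), IAA29 at -6.15 (SE 0.43), the endoglucanase gene GH9B13 at -5.25 (SE 0.35), RL3 at -5.17 (SE 0.22, adjusted p = 2.3e-10), ARD3 at -5.05 (SE 0.84) and CKX4, of cytokinin breakdown, at -4.99 (SE 0.27). EXPA8, GH9B13, RL3 and CKX4 were above background on 2 salt arrays. PRE1 fell at least 30.5-fold and HSD2 at least 12.9-fold.

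Among the fixed genes, HAI1 rose by 8.48 (SE 0.59, adjusted p = 2.3e-08) at 27 h of 500 mM NaCl, DREB2A by 5.26 (SE 0.35), NCED3 by 4.97 (SE 0.40, adjusted p = 1.2e-07) and HSFA2 by 4.85 (SE 0.37). RD29B rose by 3.36, P5CS1 by 2.87, ZAT12 by 2.85, CCA1, of the clock, by 2.45 (SE 0.56, adjusted p = 0.0026), RAB18 by 2.42, NHX1 by 2.34 (SE 0.38, adjusted p = 0.00015) and PRODH1 by 1.57. RD29A rose by 1.64 (adjusted p = 0.016) and P5CDH by 1.09 (0.03). RD29A was not called after quantile normalization (0.058), with slide as a block (1.5, 0.074) or without water replicate 1 (0.06), water replicate 2 (0.071) or 500 mM replicate 1 (0.076). P5CDH was lost with slide as a block (1.06, 0.093) and without water replicate 1 (0.075), water replicate 2 (0.13), 500 mM replicate 1 (0.13) or 500 mM replicate 2 (0.11). HKT1 fell at least 1.53-fold (0.00024), but was not called with normexp (0.8). SOS1 differed by -0.29 (0.64), RBCS1A by -0.32 (0.43), TOC1 by 0.038 (0.93) and PRODH2 by 0.68 (0.28). LHCB1.3 differed by -0.70 (0.21), and was called after quantile normalization (0.0013). Without 500 mM replicate 3, LHCB1.3 (0.015) and PRODH2 (0.03) were called, and PRODH2 with normexp (0.034).

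Limma called 7645 genes for 500 mM NaCl at 27 h, with 3207 rising and 4438 falling, of which 2528 and 3255 changed at least 2-fold. The median over all genes was -0.17, -0.18 after quantile normalization and 0.016 after normexp. In the slide-blocked fit, 5954 genes were called, 4153 within slide 2, and in a fit of only both groups 4290.

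Photosynthesis genes stood lower at 27 h of 500 mM NaCl, with 29 of 38 falling (30 adjusted over the list alone, median -1.5, camera adjusted p = 2.1e-10, correlated 0.19). The antenna genes LHCB2.3, LHCB1.4 and LHCB4.2 stood at -4.14 (SE 0.31), -3.25 and -2.70. Cell cycle genes fell in 19 of 21 cases by both adjustments (median -2.3, 6.3e-08), MCM7 at -3.13, while with normexp the median was -1.1 with 11 falls. Glucosinolate genes fell in 10 of 11 cases by both adjustments (median -3, 2.2e-06, correlated 0.13), CYP83A1 at -4.04, and salicylate genes in 11 of 16 cases (12 adjusted over the list alone, median -1.9, 0.00016, correlated 0.42), PAD4 at -3.22 and ICS1 at -2.74. Senescence genes had 18 rises and 3 falls by both adjustments (median 2.3, 1.1e-07, correlated 0.052), DIN2 at 7.19, SRG1 at 4.83 and NAC092 at 4.57. ABA and dehydration induced genes had 24 rises and 1 fall by both adjustments (median 2.9, 2.1e-16), TSPO at 8.59, and all 9 PP2C genes rose by both adjustments (median 4.1, 1e-10), AHG1 at least 47.9-fold. ABA synthesis, catabolism and transport had 8 rises and 1 fall by both adjustments (median 0.99, 0.00016), CYP707A1 at 5.44. Stress transcription factors had 22 rises and 3 falls by both adjustments (median 2.6, 5.2e-10), and heat shock genes 13 rises by both adjustments (median 2, 2.5e-07), HSP70 by 4.73, the median being 1.2 with normexp.

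Redox genes had 12 rises and 6 falls at 27 h of 500 mM NaCl by both adjustments (median 0.74, camera adjusted p = 0.012, correlated 0.42), APX2 at least 10.4-fold higher. Flavonoid genes had 8 rises by both adjustments (median 0.88, 2e-04, correlated 0.13), PAP2 at 4.84. Aquaporins had 8 rises and 2 falls (8 and 3 adjusted over the list alone, median 0.6, 0.01, correlated 0.42), PIP1;4 at 2.73 and TIP4;1 at -1.99, and were not called without 500 mM replicate 3 (0.12). The clock had 7 rises and 2 falls (9 and 2 adjusted over the list alone, median 0.77, 0.0095, correlated 0.36), ELF4 at 3.05 and LHY at 2.35. Jasmonate genes had 10 rises and 4 falls by both adjustments (median 0.73, 0.044, correlated 0.42), but the call was lost with slide as a block (0.085), within slide 2 (0.07), after quantile normalization (0.069), with normexp (0.19) and without water replicate 1 (0.082) or 500 mM replicate 1 (0.054) or 3 (0.067). Lists without a call were ethylene (median 0.54, 10 rises and 6 falls, 0.16, ACS2 at 5.93), cell wall loosening (-0.77, 7 rises and 10 falls, 0.69, XTH22 at 4.28, EXPB3 at -3.89) and auxin induced genes (-0.33, 4 rises and 7 falls, 0.29, IAA19 at -3.49). Receptors had 3 rises and 3 falls (-0.21, 0.69), PYL5 at 2.06 and PYL4 at -3.43. Osmolytes had 3 rises and 1 fall with a median of -0.17 and a mean of 0.58 (0.26), RS5 at 2.89 and GOLS3 at -1.89. Ion transport had 9 rises and 4 falls with a median of -0.21 and a mean of 0.22 (0.26), SLAH3 at 3.91 and GORK at 2.27. Cytokinin regulators stood at -0.49 (0.85, ARR15 at -0.82), root markers at -0.26 with an upward test and 1 fall (0.91, CASP1 at -1), and flower or pollen markers at -0.31 (0.88, AG above background on 0 salt arrays and 1 watered array). With normexp the medians of osmolytes, ion transport, root and flower or pollen markers were 0.12, 0.087, 0.18 and 0.25. Adjusted over the list alone there were 11 rises for ethylene, 4 falls for receptors, 4 rises for osmolytes, 6 falls for ion transport and 0 falls for root markers, with the other counts of these lists the same.

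Of the 15 list calls at 27 h of 500 mM NaCl, 6 held with an estimated correlation, at an adjusted p of 0.021 for ABA-induced genes, heat shock and the cell cycle and 0.015 for ABA synthesis, PP2C and stress factors. With slides blocked, 14 held, with medians of -1.5 for photosynthesis, -2.3 for the cell cycle, -1.9 for salicylate, -3.2 for glucosinolates, 2.6 for ABA-induced genes and 2.3 for senescence, and 14 held within slide 2. The redox call was lost with normexp (0.082). DIN2 was above background on 2 watered arrays, and PYL4 and TIP4;1 on 2 salt arrays.

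**Figure D2:**
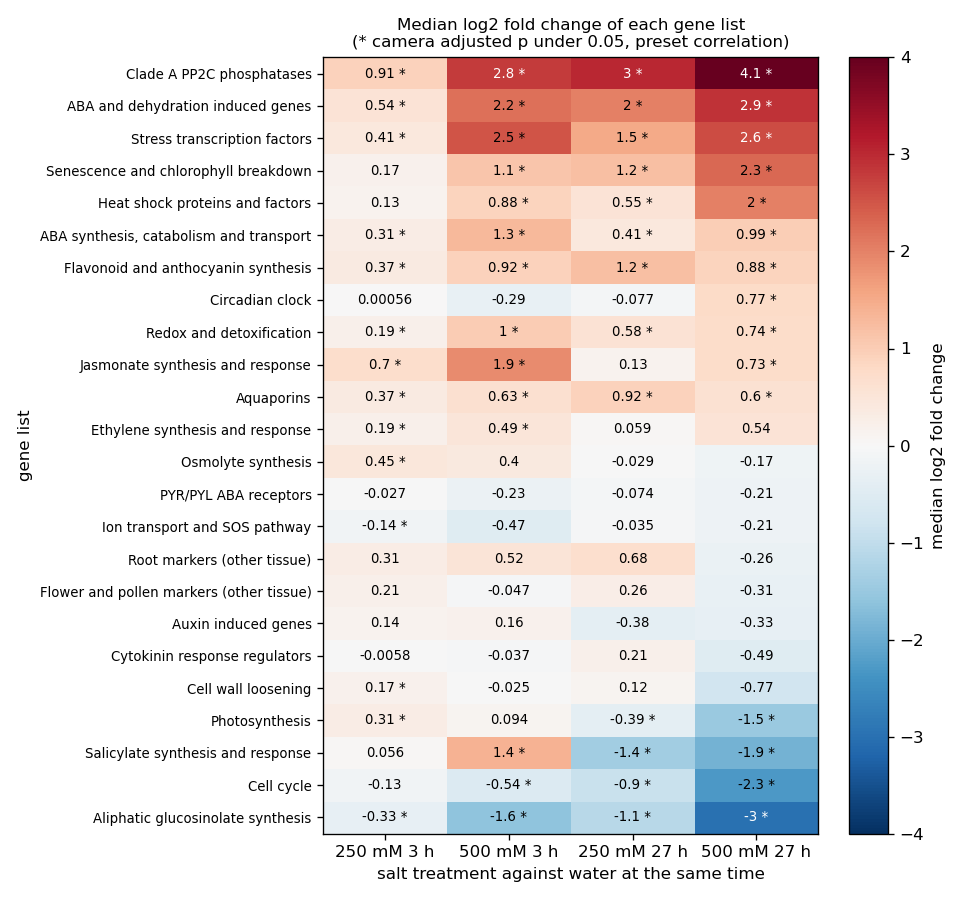
Median log2 fold change, salt against water, of the 24 gene lists (one line each) in the 4 salt comparisons (columns), with a star where the camera adjusted p was under 0.05. PP2C medians run from 0.91 to 4.1.

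The overlap of calls asked how far the responses shared genes. Of the 5442 genes called at 3 h of 500 mM NaCl, 3231 were called the same way at 27 h, 1557 rising and 1674 falling, against 406.8 and 659 expected from independent calls, and 206 went opposite ways. Across all genes both responses had r = 0.628 and a covariance of 0.945, genes not being independent replicates, and these contrasts share no arrays. At 27 h, 3636 genes were called the same way in both concentrations, 1890 rising and 1746 falling, against 326.9 and 445.7 expected, with 2 opposite. That was 90.9% of the genes called for 250 mM NaCl. Here r was 0.898 and the covariance 1.31, while 100 simulations of shared controls alone gave 0.499, 0.0721 and an overlap of 0. Between 500 mM NaCl at 3 h and 250 mM NaCl at 27 h, 2082 genes were called the same way, 1263 rising and 819 falling, against 255.6 and 294.8, and 124 went opposite ways (r = 0.649, covariance 0.725). At 3 h the concentrations had r = 0.663 and a covariance of 0.278, against 0.499 and 0.0721 from shared controls. With 3 control arrays per time the controls cannot be split into parts of at least 2, so part of the excess may come from them. In a slide-blocked fit, the overlaps were 799, 2447 and 677. Without 500 mM NaCl 3 h, replicate 1 or replicate 2, the first was 2112 or 1894, without 250 mM NaCl 27 h, replicate 3, the next was 2387, and without 500 mM NaCl 3 h, replicate 2, the last was 1380.

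The direct comparison of both concentrations at 3 h used arrays of slide 1 alone. LEA7 was higher in 500 mM NaCl by 7.80 (SE 0.91, adjusted p = 5.1e-05), UGT76E12 by 6.80 (SE 0.66, adjusted p = 1e-05), WRKY67 by 6.39 (SE 0.70, 1 array of 250 mM NaCl above background) and ELI3-2 by 5.98 (SE 0.41, adjusted p = 1.2e-06). Lower were EXPA8, at -3.36 (SE 0.45, adjusted p = 0.00017), PRE1 at -2.75 (SE 0.57, adjusted p = 0.0047), XTH33 at -2.88 with 1 array of 500 mM NaCl above background, and GA20OX3, at least 3.44-fold. With normexp XTH33 (0.24) and GA20OX3 (0.3) were not called, and without 500 mM NaCl 3 h, replicate 2, PRE1 was not (0.06). HAI1 was higher by 4.87, HSFA2 by 4.03 (adjusted p = 6.4e-06), PRODH2 by 2.79 and NCED3 by 2.61. NHX1 was higher by 1.29 (0.032), though not with slide as a block (0.057) or without any 1 of 250 mM replicates 1 to 3 (0.059, 0.094, 0.1) or of 500 mM replicates 1 and 2 (0.1, 0.15). Limma called 3171 genes, 1715 higher and 1456 lower, 2836 within slide 1 and 2405 with slide as a block, and the median of all genes was -0.13. Without 250 mM NaCl 3 h, replicate 2, the count was 1626, and without 500 mM NaCl 3 h, replicate 1 or replicate 2, 1567 or 1575. Without the dimmest arrays of 27 h, which enter only through the shared spread, it was 5004.

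Lists stood higher in 500 mM than in 250 mM NaCl at 3 h for stress transcription factors (median 2, 23 rises, 24 adjusted over the list alone, camera adjusted p = 7.2e-18), ABA-induced genes (1.7, 16 rises, 17 adjusted over the list alone, 8.4e-18), PP2C (2.2, 8 rises, 9 adjusted over the list alone, 4.1e-10) and jasmonate (1.3, 17 rises, 18 adjusted over the list alone, 5.6e-12). Senescence (1.2, 13 rises, 1.7e-08, SAG12 at 4.83 with 2 arrays of 250 mM NaCl above background) and ABA synthesis (1.2, 7 rises and 1 fall, 5.7e-05) were higher as well. These 6 of 14 calls held with an estimated correlation, at 0.0032, 0.014, 0.012, 0.012, 0.043 and 0.0093. Salicylate (1.4, 6 rises, 1.3e-06, correlated 0.26, ICS1 at 2.37), redox (1, 11 rises, 1.3e-07, correlated 0.098, GSTU3 at least 22.6-fold), heat shock (0.72, 8 rises, 8.2e-05, correlated 0.065), ethylene (0.36, 9 rises and 1 fall, 0.00017, correlated 0.068) and flavonoids (0.66, 3 rises, 0.00033, correlated 0.14) were higher by camera. Glucosinolates (-1.1, 5 falls, 0.00031, correlated 0.26), the cell cycle (-0.45, 1 fall, 0.017, correlated 0.26) and photosynthesis (-0.23, 3 falls, 0.021, correlated 0.7) were lower. Adjusted over the list alone, rises numbered 15 in senescence, 14 in redox, 11 in salicylate, 9 in heat shock and ethylene (2 falls), 8 in ABA synthesis (1 fall) and 4 in flavonoids (1 fall), and falls 5 in glucosinolates, 3 in photosynthesis and 1 in the cell cycle. Both groups lay on slide 1, so the 14 calls kept with slide as a block or within that slide, at medians fixed by the design, test no slide effect. Photosynthesis was lost with fry (0.17) and without 250 mM replicate 1 (0.3) or 500 mM replicate 3 (0.27) and the cell cycle without 500 mM replicate 2 (0.1). Aquaporins were called after quantile normalization (0.04), within slide 1 (0.048) and without 250 mM replicate 1 (0.016) or 500 mM replicate 1 (0.031). With normexp 3 glucosinolate genes were called.

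At 27 h, DIN2, a dark-inducible glucosidase gene, was higher in 500 mM than in 250 mM NaCl by 3.91 (SE 0.61, adjusted p = 0.0011), LCR67 by 3.36 (SE 0.78, adjusted p = 0.015, 1 array of 250 mM NaCl above background), MPL1 at least 7.28-fold and APX2 at least 8.55-fold. EXPB3 was lower, at -3.48 (SE 0.28, adjusted p = 7.4e-06), GH9B13 at -3.30 (SE 0.35) and LHCB2.3 at -2.63 (SE 0.31), while SP1L5 was at least 5.79-fold and PRE1 at least 3.09-fold lower. DREB2A was higher by 2.14 (adjusted p = 0.0018), PRODH1 by 1.5 (0.031) and CCA1 by 1.96 (0.042), while HAI1 and NCED3 each differed by 1.2 (0.25 and 0.084). With slide blocked, PRODH1 (0.058) and CCA1 (0.076) were lost, CCA1 after quantile normalization too (0.062). Without any 1 of the arrays other than 500 mM replicate 3 CCA1 was lost (0.065 to 0.15), and PRODH1 without 250 mM replicates 1 and 3 (0.13, 0.089) or 500 mM replicates 1 and 2 (0.11, 0.051). LCR67 was lost without 250 mM replicates 1 and 3 (0.068, 0.057) and 500 mM replicate 1 (0.076), and with normexp LCR67 (0.079), SP1L5 (0.054) and PRE1 (0.37) were not called. Limma called 1617 genes, 587 higher and 1030 lower, 1103 with slide as a block, 132 within slide 2 and 101 in a fit of both groups alone. Without 250 mM replicates 1, 2 and 3 in turn the counts were 782, 859 and 1075, and without 500 mM replicate 1 795. Without 500 mM replicate 3, the dimmest array, 4529 were called, and without it and the dimmest watered array, 5367.

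Photosynthesis genes lay lower in 500 mM than in 250 mM NaCl at 27 h (median -0.99, 23 falls, 32 adjusted over the list alone, camera adjusted p = 6.7e-20, correlated 0.062). So did the cell cycle (-1.1, 7 falls, 15 adjusted over the list alone, 1.3e-10), glucosinolates (-1.8, 5 falls, 8 adjusted over the list alone, 1.6e-08, correlated 0.069, CYP83A1 at -2.76), cell wall loosening (-0.96, 9 falls, 1e-04, correlated 0.44) and aquaporins (-0.44, 1 fall, 0.034, correlated 0.52). Heat shock (0.98, 6 rises, 12 adjusted over the list alone, 7.9e-09, HSP70 at 2.38), senescence (0.91, 8 rises, 7.9e-09), stress factors (0.94, 7 rises, 3.7e-07), PP2C (1.1, 4 rises, 2.6e-06), ABA-induced genes (0.83, 3 rises, 3.7e-05, correlated 0.22), the clock (0.61, 3 rises, 9.6e-05, correlated 0.14, LHY at 2.43) and ABA synthesis (0.53, 3 rises, 0.00089, CYP707A4 at 1.78) were higher. With an estimated correlation 6 held, at 0.023 for heat shock and the cell cycle, 0.042 for senescence and PP2C, 0.04 for stress factors and 0.025 for ABA synthesis. Adjusted over the list alone, rises numbered 10 in senescence, 9 in stress factors, 6 in ABA-induced genes (1 fall), 5 in PP2C and ABA synthesis and 4 in the clock, and falls 13 in cell wall loosening (1 rise) and 4 in aquaporins (1 rise). Both groups lay on slide 2, so the 12 calls kept with slide as a block or within it, at fixed medians, test no slide effect. The aquaporin call was lost with fry (0.2), after quantile normalization (0.056) and without 250 mM replicate 1 (0.055) or 3 (0.056) or 500 mM replicate 1 (0.46). With normexp the medians were -0.5 for the cell cycle (2 falls), -0.88 for glucosinolates (3 falls) and -0.57 for cell wall loosening, with 3 heat shock and 5 senescence genes called, and with slide as a block 5 senescence genes and 1 ABA-induced gene were called. Salicylate was called without 250 mM replicate 1 (0.043) or 3 (0.027) or 500 mM replicate 1 (0.00022) or 2 (0.045) and within slide 2 (0.039), cytokinin regulators without 500 mM replicate 3 (0.041) and within slide 2 (0.042), redox without that array (0.036) and after quantile normalization (0.048), ethylene with normexp (0.028), and root markers without 500 mM replicate 3 (0.01) or 250 mM replicate 2 (0.022).

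**Figure D3:**
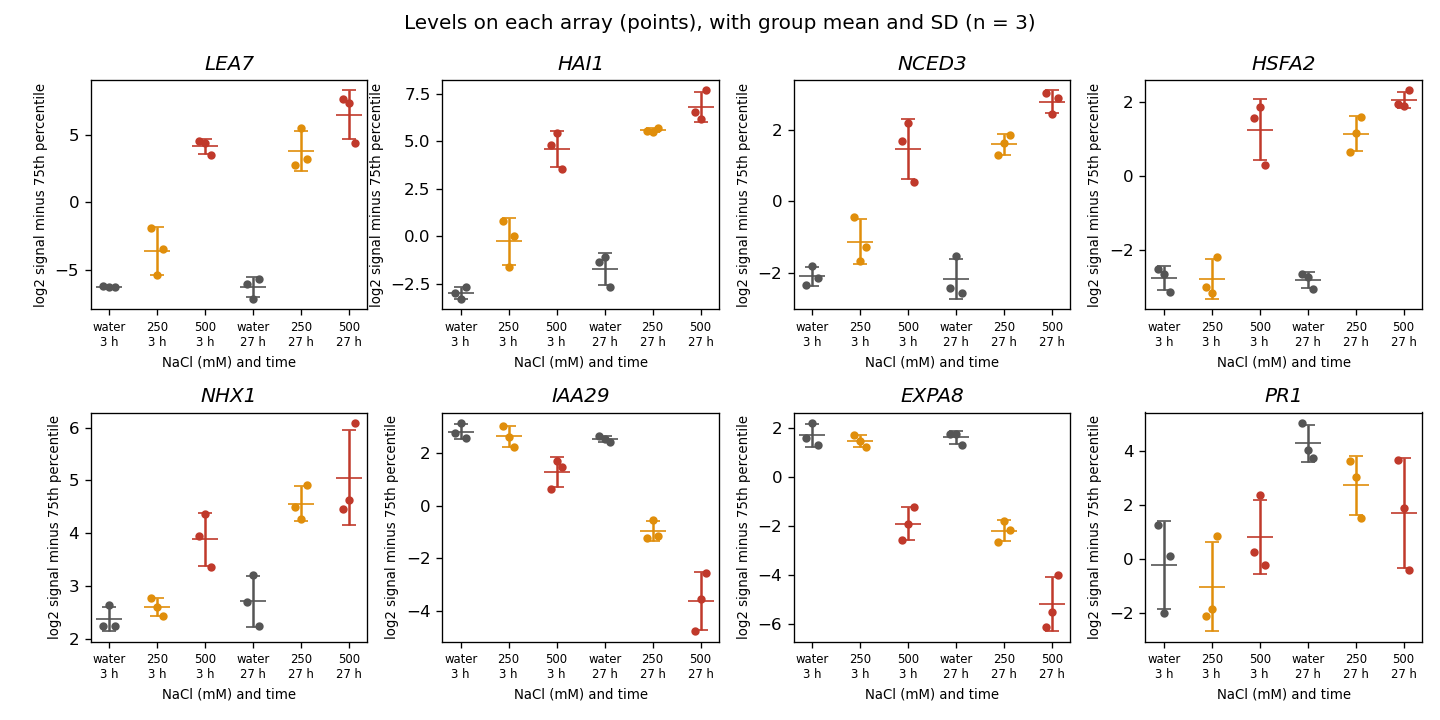
Log2 signal relative to the 75th percentile of each array for LEA7, HAI1, NCED3, HSFA2, NHX1, IAA29, EXPA8 and PR1, with a point per array and the mean and SD per group (n = 3), genes chosen for display after their values were seen. At 27 h LEA7 stands higher after salt and IAA29 and EXPA8 lower, both with their lowest group means in 500 mM NaCl.

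Whether the salt response itself differed between the times was tested as an interaction. For 250 mM NaCl, LTP4 responded more at 27 h by 8.30 (SE 0.50, adjusted p = 4.8e-07), HAI1 by 4.58 (SE 0.83, adjusted p = 0.0033) and HSFA2 by 3.95 (SE 0.53, adjusted p = 0.00029). For 500 mM NaCl, ICS1 stood at -5.29 (SE 0.74, adjusted p = 0.00028) and FMO1 at -5.72 (SE 1.2, adjusted p = 0.0048). ICS1 rose at 3 h and fell at 27 h. The jasmonate genes TAT3 and AOC3 stood at -6.05 and -4.83, the stress factor WRKY53 at -5.28 and LHCB2.3 at -3.44 (adjusted p = 0.00013). FMO1 and WRKY53 were above background on 2 arrays of 500 mM NaCl at 27 h. Limma called 1068 genes for 250 mM NaCl, 678 with a higher and 390 with a lower change at 27 h, and 2385 for 500 mM NaCl, 883 higher and 1502 lower. Of these, 923 and 2139 were above background on some array of each group, and for the others the difference has no measured value. In the slide-blocked fit, the counts were 232 and 577, and no slide held all the groups. The 250 mM count was 709 without water 3 h, replicate 2, 705 and 707 without 250 mM NaCl 3 h, replicates 2 and 3, and 666 without 250 mM NaCl 27 h, replicate 3. The 500 mM count was 3805 without 500 mM NaCl 27 h, replicate 3. Without both watered 3 h arrays of high control signal, which leaves 1, they were 369 and 1091, and without the dimmest arrays the 250 mM count was 2070. HAI1 for 250 mM NaCl was not called with slide as a block (4.74, 0.063).

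The watered plants at both times gave the background against which the salt responses stood. XTH10, of the cell wall, was higher at 27 h than at 3 h by 4.16 (SE 0.64, adjusted p = 0.015), GLP9 by 4.15 (SE 0.70, adjusted p = 0.021, 2 arrays of 3 h above background), RSH4 by 4.27 (SE 0.89, adjusted p = 0.042, 1 array of 3 h above background) and ARD3 by 4.11 (SE 0.84, adjusted p = 0.041). The iron-related genes ORG1 and PYE were lower, at -1.97 (SE 0.39) and -1.62 (SE 0.26), ZW9 at -1.39 and the wax gene WSD1 at -1.37. Also higher were ZAT7 at 3.58, ZAT12 at 3.14 (adjusted p = 0.048), SAG13 at 3.03, SAG14 at 2.17 and CAX3 at 2.01. PR1, a salicylate marker, differed by 4.49 (SE 1.1, adjusted p = 0.066). Limma called 133 genes, 122 higher and 11 lower at 27 h, but 1 with slide as a block and 0 within slide 1, where 1 array stood in each group and 1427 genes had an unadjusted p under 0.05. None of the named genes was called with slide as a block (0.77), where XTH10 stood at 4.2, GLP9 at 4.31, RSH4 at 3.09, ARD3 at 3.35, ORG1 at -1.92 and PYE at -1.52. Called genes kept a slope of 0.94 there with the same signs, and the SE grew by a median of 1.85 times, so precision was lost. Without water 3 h, replicates 1, 2 and 3 in turn, the counts were 57, 2 and 1, and without water 27 h, replicates 1, 2 and 3, 1, 1 and 743. These arrays met the bound for pairing, though not each matched best by its own number, and the labels state no pairing. The replicate block gave 69 genes and lost RSH4 (0.076), ARD3 (0.059), ORG1 (0.056), ZW9 (0.073) and ZAT12 (0.088). Quantile normalization lost RSH4 (0.093) and ORG1 (0.051). The 4 largest changes in each direction and ZAT12 were lost without water 3 h, replicate 2 or 3, and without water 27 h, replicate 1 or 2 (0.083 to 0.3), and ORG1, ZW9, WSD1 and ZAT12 also without water 3 h, replicate 1 (0.06 to 0.1).

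Of the 24 lists, camera called 8 between the watered groups, and none held with an estimated correlation, where senescence had an adjusted p of 0.55 and the other 7 had 0.48, or with fry (0.13 to 0.19). Salicylate genes lay higher at 27 h (median 1.5, camera adjusted p = 3e-06) with 0 called over all genes and 12 of 16 rising adjusted over the list alone. Redox genes lay higher (0.76, 12 rises adjusted over the list alone, 2.4e-05, OXI1 at 2.2), as did root markers (0.97, 2 rises adjusted over the list alone, 0.023, NRT2.1 at 2.34 with 1 array of 3 h above background), PP2C (0.59, 3 rises adjusted over the list alone, 0.044) and senescence (0.27, 2 rises, 5 adjusted over the list alone, 0.044). Glucosinolates (-0.72, 4 falls adjusted over the list alone, 0.00045, CYP79F1 at -1.21), auxin induced genes (-0.51, 0.044) and the cell cycle (-0.36, 0.044) lay lower, the last 2 with 0 falls by both adjustments. With slides blocked, which compares 1 watered array with 1, the medians were 0.98 for redox, 0.31 for senescence, 0.94 for salicylate and -1.3 for glucosinolates. The calls of PP2C, auxin, root markers and the cell cycle were lost there, and photosynthesis, cytokinin regulators and aquaporins gained a call. Normexp ended the PP2C (0.16), senescence (0.16), cell cycle (0.12) and root marker (0.087) calls, and quantile normalization PP2C (0.086) and the cell cycle (0.09), with photosynthesis called downward (0.028). With the replicate block redox, salicylate, glucosinolates and root markers held. Salicylate, redox and glucosinolate calls held with each array left out. Without water 3 h replicate 1, PP2C and auxin (each 0.057) were lost, without its replicate 2 PP2C (0.079), auxin (0.12), the cell cycle (0.09), senescence (0.11) and root markers (0.056), without water 27 h replicate 1 senescence (0.11), without its replicate 2 PP2C (0.091), auxin, the cell cycle and root markers (each 0.092), and without its replicate 3 PP2C, auxin, the cell cycle (each 0.06) and senescence (0.093).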

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

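The tests of signal strength, of an uneven salt response, of both explanations for the lower count at 500 mM NaCl and of higher salicylate genes in watered plants were chosen only after the result was seen.

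The results here stand out because the response to the same salt concentration differed between 3 h and 27 h by a test of that difference, or because a signal appeared on probes that the comparisons of genes do not use. Values are the response at 27 h minus that at 3 h on the log2 scale, from 3 arrays per group. For 250 mM NaCl the test called 1068 genes and for 500 mM NaCl 2385, of which 923 and 2139 were above background on some array of each of the 4 groups. Values are given for these alone.

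At 250 mM NaCl positive differences between the times included SAG29 at 8.58, LTP4 at 8.30, GLYI7 at 7.76, LEA7 at 7.49, TSPO at 6.89, LEA4-5 at 6.47, ELI3-2 at 6.34, HAI1 at 4.58, CYP94B3 at 4.11, UGT76E12 at 4.02 and HSFA2 at 3.95. GPAT5, of suberin synthesis, differed by 3.6, WSD1 by 3.17, DREB2A by 3.13, NCED3 by 2.80, RAB18 by 1.95 and ZW9 by 1.61. Negative differences were those of the defensins PDF1.2b at -3.82 and PDF1.2 at -3.76, GLL22 at -3.74, EXPA8 at -3.57, CYP81F2 at -3.56, XND1 at -3.46, IAA29 at -3.31, PRE1 at -3.20, RL3 at -2.69, CKX4 at -2.54 and GH9B13 at -2.25. In at least 1 of the 4 groups LEA7, UGT76E12, GPAT5 and XND1 were above background on only 1 array, and GLYI7, CYP81F2 and GLL22 on 2. In a slide-blocked fit, LEA7 (7.7, adjusted p = 0.053), HAI1 (4.74, 0.063), GLL22 (-3.43, 0.13), EXPA8 (-3.62, 0.068), RAB18 (1.7, 0.22) and NCED3 (2.43, 0.22) were not called, the SE growing by a median of 1.36 times, and with normexp GLL22 (0.17) was not.

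By list, the 250 mM NaCl response was higher at 27 h for PP2C, with a median of 2 and 6 genes called (camera adjusted p = 4.8e-12), ABA-induced genes at 1.8 with 11 (5.6e-18), stress factors at 1.1 with 6 and 2 in the other direction (3.1e-06), senescence at 1.1 (5.6e-06), flavonoids at 0.87 (8.8e-05), aquaporins at 0.58 (0.00012), heat shock at 0.36 (0.0037) and ABA synthesis at 0.29 (0.0037). With an estimated correlation PP2C (0.019) and ABA-induced genes (0.031) held, while ABA synthesis stood at 0.05, stress factors at 0.057 and the other 9 between 0.14 and 0.56. The response was lower for salicylate at -1.5 (6.7e-06), glucosinolates at -0.87 (0.037), photosynthesis at -0.76 (5.8e-07), the cell cycle at -0.69 (0.0039) and auxin induced genes at -0.48 (0.0051). With slide blocked, all 13 held, with medians of 2 for PP2C, 1.7 for ABA-induced genes, -1.1 for salicylate and -1.1 for photosynthesis. Fewer members were called there, 6 ABA-induced genes, 1 PP2C gene, 2 stress factors and 0 photosynthesis, salicylate, aquaporin or auxin genes. Glucosinolates were lost after quantile normalization (0.05), with normexp (0.09, median -0.44) and without water 3 h, replicate 2 (0.051), 250 mM 3 h, replicate 2 (0.097), water 27 h, replicate 3 (0.27) or 250 mM 27 h, replicate 3 (0.073), and the cell cycle with normexp (0.052, median -0.27). Photosynthesis was at -0.46 with 1 gene called after quantile normalization. Redox was called without 250 mM 3 h, replicate 3 (0.038). With fry salicylate (0.075), aquaporins (0.1) and glucosinolates (0.22) were lost.

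At 500 mM NaCl SAG29 differed by 7.72, GPAT5 by 6.34, DIN2 by 4.78, GLYI7 by 4.19 and LTP4 by 3.80. DREB2A differed by 2.80, the iron-related genes PYE and ORG1 by 2.39 and 2.12, RAB18 by 2.16 and P5CDH by 1.71. Strongly negative were UGT76B1, of salicylate and isoleucic acid conjugation, at -7.42, WRKY38 at -7.15, ARD3 at -7.15 and RSH4 at -7.12. GH9B13 stood at -5.06, PDF1.2b and IAA29 each at -4.61, PDF1.2 and CKX4 each at -4.59, GLP9 at -4.57, EXPB3 at -3.96 and RL3 at -3.85. EXPA8 stood at -3.20, DIN11 at -2.75, PRODH2 at -2.70 and CYP81F2 at -2.10. In the slide-blocked fit, ARD3 (-5.89), RAB18 (1.92), PRODH2 (-2.01) and P5CDH (1.69) were not called. P5CDH was lost after quantile normalization (0.053), with normexp (0.052) and with most of the 12 arrays left out in turn (0.063 to 0.12). In at least 1 of the 4 groups GPAT5 and RSH4 were above background on only 1 array, and DIN2, GLYI7, UGT76B1, WRKY38, GH9B13, CKX4, GLP9, RL3, EXPA8, DIN11, PRODH2 and CYP81F2 on 2.

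By list, the 500 mM NaCl response was lower at 27 h for salicylate, with a median of -3.8 and 14 of 16 genes called (camera adjusted p = 5.4e-14), glucosinolates at -1.6 (0.0019), photosynthesis at -1.4 with 24 genes called (1.1e-15), the cell cycle at -1.4 (8.3e-07), jasmonate at -1.1 with 12 genes called (3.2e-07) and auxin induced genes at -0.31 (0.01). With an estimated correlation none held, the adjusted p running from 0.13 to 0.36. The response was higher for PP2C at 1.1 (5e-04), ABA-induced genes at 0.84 (0.0011), senescence at 0.78 (0.0063), heat shock at 0.71 (0.0037) and the clock at 0.49 (0.01). With slides blocked, all 11 held, salicylate at -3 and photosynthesis at -1.8, with 5 and 14 genes called, and jasmonate had 7, the cell cycle 3 and heat shock 0. Glucosinolates were lost with normexp (0.051, median -0.75), where the cell cycle was at -0.38 with 1 gene called and heat shock had 2, and photosynthesis was at -0.92 with 17 genes called after quantile normalization. The clock was lost without 500 mM 27 h, replicate 1 (0.051). Redox was called with normexp (0.032) and without that array (0.034) or 500 mM 3 h, replicate 3 (0.025), and ethylene without the latter (0.028), water 27 h, replicate 3 (0.047) or 500 mM 27 h, replicate 2 (0.048).

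Probes matched to no locus carried a signal of the same kind. Of 4533 such probes above background, limma called 1 for 250 mM NaCl at 3 h, 544 for 500 mM NaCl at 3 h, 519 for 250 mM NaCl at 27 h and 1192 for 500 mM NaCl at 27 h. What these probes detect is not given in the sources used here.

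Other splits of the same arrays were counted. For both interactions 6 of 100 splits, the real one included, gave as many genes, so chance is not excluded by them. At 250 mM NaCl the real split gave 1779 in a fit of those 4 groups and the highest other 2452, and the 5 others as large kept the 27 h groups whole. At 500 mM NaCl the real split gave 1519 and the highest other 8067, a split that exchanges salt and water at 1 time and so adds the responses, while 4 others kept 1 time whole. Splits that mixed both times gave at most 20 and 0 genes. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. There the real and highest other counts were 4976 and 0 for 500 mM NaCl at 3 h, 3919 and 0 for 250 mM NaCl at 27 h, 4290 and 0 for 500 mM NaCl at 27 h, 2836 and 0 and 101 and 0 for the concentrations at 3 h and 27 h, and 145 and 0 for the watered groups, each with 1 split as large. For 250 mM NaCl at 3 h the real count was 0, as in all 10 splits. In the contrasts that met the pairing bound, the 3 other splits that part every pair gave 0 as well.

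Arrays of 1 group differed along 1 main axis that held 53.2% of the variance within groups. The position on it followed the signal strength of the array, the log2 75th percentile less the group mean, with r = 0.95 (permutation p = 0.00046) and rho = 0.94 (permutation p = 0.00029) over 18 arrays, 1 relation tested, and r = 0.9 without the 2 farthest arrays. An uneven salt response is argued against, as salt-array and watered-array loadings correlated at 0.81 across genes. An earlier test, absolute r with the mean salt response, gave 0.3 for salt arrays, between its bounds, and 0.42 for watered arrays. The axis partly resembles that response, and 0.81 was added later. Median loading percentiles of the lists ran from 5.85 for root markers to 82.6 for glucosinolates. PP2C stood at 21, aquaporins at 22.1 and salicylate at 79.4, and whether list calls carry signal strength was not tested. Transcript length correlated with the loading at 0.41 over 19765 genes, so RNA breakdown or uneven labelling may contribute, and no biological explanation beyond the salt response was tested.

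The count for 500 mM NaCl at 3 h was 5442 and 985 with slide as a block. Changes of called genes kept a slope of 0.99 there, all with the same sign. The SE grew by a median of 1.51 times, as lost precision would give. Part of that is fixed by a block leaving 1 watered array beside the salt arrays. That watered array lay 0.025 of the way to the 500 mM group over the 5442 genes, against 0.039 and -0.014 for the arrays of slide 3. Resting on 1 array, this does not decide whether slides differed. The salt response itself stays open as the biological explanation of the calls.

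Salicylate genes stood lower in salt than in water at 27 h and higher at 3 h of 500 mM NaCl by camera, calls that were lost with an estimated correlation, at an adjusted p of 0.41 and 0.42 at 27 h and 0.3 at 3 h, where 0 members were called with slide as a block. A slide difference as the whole cause is argued against, since the slide-blocked medians were -1.9 for 500 mM and -1.3 for 250 mM NaCl. The watered plants had higher salicylate genes at 27 h by 1.5, and by 0.94 with slide as a block, and set against water at 3 h the salt arrays of 27 h stood at -0.54 and -0.11. Whether watered plants rose or salted plants fell is not settled by these values, and the handling of the watered plants at each time is not given.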

How the results depend on the processing

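The fits without arrays that stood apart, with array weights and with signal strength as a covariate were chosen only after the result was seen.

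Each count is given under the settings that moved it more than 1.5 times, and the cause was not tested unless stated. For 500 mM NaCl at 3 h, 5442 genes became 985 with slide as a block, 708 within 1 slide, 1457 without both watered arrays of high control signal, 13599 with array weights and 2541 at an adjusted p under 0.01, with 2626 to 6732 when 1 array was left out. For 250 mM NaCl at 27 h, 4000 became 2617 with slide as a block, 1319 within 1 slide, 7190 without the dimmest arrays, 9132 with weights and 2228 at 0.01 (2500 to 4210). For 500 mM NaCl at 27 h, 7645 became 4290 with only the groups compared, 4153 within 1 slide and 11477 with weights (6373 to 8461). For 250 mM NaCl at 3 h, 0 became 1791 with weights (0 to 2). For 500 against 250 mM NaCl at 3 h, 3171 became 5004 without the dimmest arrays, 12897 with weights, 5784 with the covariate and 1461 at 0.01 (1567 to 4417). At 27 h, 1617 became 970 with normexp, 101 with only the groups compared, 132 within 1 slide, 5367 without the dimmest arrays, 7164 with weights, 4063 with the covariate and 589 at 0.01 (782 to 4529). For the change of the 250 mM response, 1068 became 680 with normexp, 1779 with only the groups compared, 232 with slide as a block, 2070 without the dimmest arrays, 369 without the watered arrays of high control signal, 5539 with weights, 2346 with the covariate and 483 at 0.01 (666 to 1041). For 500 mM, 2385 became 1578 with normexp, 1519 with only the groups compared, 577 with slide as a block, 1091 without the watered arrays of high control signal, 9563 with weights, 4599 with the covariate and 1243 at 0.01 (1737 to 3805). For the watered groups, 133 became 47 without a filter, 1 with slide as a fixed block, 326 as a random block, 0 within 1 slide, 69 with the replicate block, 2 without the dimmest arrays, 0 without those of high control signal, 11571 with weights and 1 at 0.01 (1 to 743). Fewer calls at 0.01 follow from the stricter threshold. Overlaps were 799 for 500 mM NaCl at 3 h and 27 h and 677 for 500 mM at 3 h and 250 mM at 27 h with slide as a block, and 1894 to 3527, 2387 to 3713 for both concentrations at 27 h, and 1380 to 2213 with 1 array left out.

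Signs turned for HKT1 at 27 h of 250 mM NaCl with normexp (0.0311), for the salicylate list at 3 h of 250 mM NaCl with slide as a block (adjusted p = 0.01), within 1 slide (0.014) and without 250 mM NaCl 3 h, replicate 3 (0.028, the range with 1 array left out being 0.011 to 0.86), and for the photosynthesis list after quantile normalization at 3 h of 250 mM NaCl (0.82) and between the watered groups (0.028). Of 259 named gene results, 249 stayed on the same side of the threshold after quantile normalization, 241 with normexp, 226 with slide as a block and 251 with the replicate block. Of 216 list results, 204, 201, 203 and 210 did, 182 with fry and 134 with an estimated correlation. The replicate block moved no other count of genes beyond 1.5 times. An array left out leaves 2 in its group, and the fits without the watered arrays of high control signal leave 1, assumed to vary like the others. The interactions were not run within 1 slide, since no slide held the groups. Genes near background limit the folds, where normexp shrank falls of dim genes.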
